A study of Oryza sativa Japonica Group with 9 samples.

How the data were processed

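RNA from whole seedlings of 9 samples, 3 each of control, vacuum and ion beam (nitrogen ions), all at 96 h, was measured on single-colour Agilent arrays. Per the labels, the authors extracted RNA with TRIZOL and RNeasy columns with DNase treatment and labelled it with Cy3 using a low-input one-colour kit. The deposited scanner files hold spot intensity, and per the file headers they were made by Agilent Feature Extraction 10.5.1.1, with background subtraction, spatial and multiplicative detrending, surrogate values for dim spots and no scaling between arrays. The deposited value table holds the same processed intensity on a linear, uncentred scale: its largest difference from the scanner files was 0. Its column medians over all spots were 1098, 1240 and 1105 for controls 1 to 3, 1474, 1290 and 1262 for vacuum 1 to 3, and 1361, 1301 and 1505 for ion beam 1 to 3. Slide and position were read from the scanner files, which show 1 scan per slide.

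The deposited files were analysed in R 4.3.3 with limma 3.58.1; tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Processed signals were log2-transformed, the 75th percentile of each array was subtracted, and repeat spots of a probe were averaged. Control spots and spots with an outlier mark from the scanner software were dropped (67 probes had at least 1 such spot); between 14 and 44 gene spots per array carried the mark and 0 were saturated. Of 42418 gene probes, the 34904 that were well above background on every array of at least 1 group were tested, and 32742 of them were so on all 9 arrays. Each 60-base probe was assigned to a locus by the annotation inside the scanner files (29689 loci on the array, 529 probes with none), and gene descriptions are those of that annotation. Chromosome numbers were taken from the locus names.

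One limma linear model with empirical Bayes moderation covered the 3 groups (6 residual and 2.54 prior degrees of freedom; 4 residual degrees of freedom with slide as a block). The 3 two-sided contrasts were tested, with Benjamini-Hochberg adjustment over the probes of each contrast and a threshold of 0.05. Fold changes are differences of group means with the moderated standard error, and SDs are between the arrays of a group. A fold is given as at least N-fold where one group had no array well above background, with the lowest above-background signal of each array, or the probe's own where higher, in place of that group's values. A set of 37 lists of genes, fixed from description words, were tested with camera at a preset correlation of 0.01, one probe a gene, for lists of at least 5 genes, with adjustment over all lists and contrasts together. Groups, contrasts, tests, lists, alternatives and the rule for naming genes were set before the data were examined.

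Genes were named by this rule: in each contrast, among described genes with one probe each, the 10 highest and 10 lowest log2 fold changes with an adjusted p under 0.05, then the 3 smallest p of each list that camera called or that held at least 3 changed genes. Which of the lists have genes named in the text, and the genes drawn in the figures, were chosen after the values were seen. The alternatives covered background correction with normexp (offset 50), quantile normalization, median centring, the value table, filters for dim and marked spots, slide or replicate number as a block, 1 slide alone, 2 groups alone, other variance models, array weights, one probe a gene, a plain t-test, a 2-fold limit, an estimated correlation, the fry test, and each array left out in turn. Counting the 3 controls as 1 sample and adding the last position on a slide as a covariate were chosen after seeing the data.

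Precision was tested on simulated data with the spread of these arrays, with 50 changed probes per fold. Changes of 1.2-fold were called in 8% (ion beam against control), 0% (vacuum against control) and 10% (ion beam against vacuum) of the probes, 1.5-fold in 70%, 66% and 56%, 2-fold in 90%, 92% and 94%, and 4-fold in 96%, 98% and 92%. False calls numbered 11, 6 and 5 among the unchanged ones of the 34904 probes. Far fewer probes were changed here than passed in the real contrasts (51.5%, 22.5% and 23.3%). The adjusted threshold depends on that share, so these rates do not carry over to the real contrasts. With 1 of 37 simulated lists shifted, camera called that list and 0 of the others. The simulated genes varied independently of each other, so false calls from correlated genes were not tested. In the real data the correlation estimated within a list was 0.4 for histones and 0.24 for ribosomal proteins.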

Results

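Transcripts were measured in whole seedlings of rice (Oryza sativa, Japonica group) raised from 3 kinds of dry seed: seeds implanted with a beam of nitrogen ions, seeds given a vacuum treatment, and untreated controls. Ion beam implantation drives accelerated ions into the seed inside a vacuum chamber and is used in plant breeding to induce mutations. Seedlings grew in the dark at 28 °C on 0.8% agar and were sampled at 96 h. Each group held 3 samples, and each sample was hybridised to 1 single-colour Agilent oligonucleotide array of 45151 spots. Between 77.7% (vacuum 1) and 85.9% (vacuum 3) of the 43144 gene spots on an array were well above background. The median processed signal of an array ranged from 1314 (control 1) to 1771 (ion beam 3). The tests covered 34904 probes of 24052 genes. Arrays of one group correlated more closely (mean r across probes 0.998 in controls, 0.994 in vacuum and 0.995 in ion beam seedlings) than arrays of different groups (0.990 for control with vacuum, 0.989 for ion beam with vacuum, 0.985 for control with ion beam). Probes are not independent replicates. The arrays came from 3 slides: slide 1 held the 3 ion beam arrays and control 3, slide 2 held controls 1 and 2 with vacuum 2 and 3, and slide 3 held vacuum 1. The labels do not say that the samples of a group were grown as separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

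Seedlings from implanted seeds were first compared with untreated controls, a contrast that takes in both the ions and the vacuum. Transcripts of core and linker histones, the proteins that package DNA, and of ribosomal proteins were lower in ion beam seedlings. Of 49 histone genes 43 fell and 6 did not pass, with a median log2 fold change of -0.53 (SD between genes 0.24). Of 297 ribosomal protein genes 224 fell, 30 rose and 43 did not pass, with a median of -0.39 (SD 0.30). Genes of NB-ARC disease resistance proteins, intracellular immune receptors, moved the other way: 68 of 177 rose, 13 fell and 96 did not pass, with a median of 0.22. Over all 24052 genes, one probe a gene, 6428 were higher and 5794 lower. Proteasome subunits, which form the complex that degrades ubiquitin-tagged proteins, included 23 genes that fell and 4 that rose among 54. Lipid transfer proteins, which carry lipids to the cell surface, included 25 that fell and 6 that rose among 64. Among the histones, an H4 gene (Os09g0433600) had a log2 fold change of -0.66 ± 0.06 (SE, n = 3 and 3; limma adjusted p = 0.000172) and an H3 gene (Os06g0160100) one of -0.55 ± 0.06. The ribosomal protein L37 gene Os02g0815000 fell (-0.62 ± 0.05, adjusted p = 0.000145), as did that of chloroplast L12 (Os01g0662300, adjusted p = 0.000176; 1.59 ± 0.09 to 0.59 ± 0.05, SD). The gene of chloroplast S1 (Os03g0315800) was among the 30 that rose (0.64 ± 0.06). Examples from the other lists were the NB-ARC genes Os11g0605100 (1.41 ± 0.09, adjusted p = 6.95e-05) and Os10g0183000 (1.07 ± 0.06) and the proteasome alpha type 4 gene Os06g0176000 (-0.52 ± 0.07). Lipid transfer protein genes that fell were Os12g0114500 (-1.35 ± 0.15) and Os06g0705400 (-0.81 ± 0.08, where only 1 of the gene's 2 probes was lower).

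When adjusted over the list alone, 43 histone genes fell, and 228 ribosomal protein genes fell and 32 rose. In the same adjustment 65 NB-ARC genes rose and 13 fell, 23 proteasome genes fell and 4 rose, and 25 lipid transfer genes fell and 6 rose. The camera test of limma, which sets each list against all other genes at a preset correlation of 0.01, gave adjusted p = 2e-13 for histones, 6.15e-16 for ribosomal proteins, 0.00125 for NB-ARC proteins, 0.0105 for the proteasome and 0.011 for lipid transfer proteins. With a correlation estimated within each list all 5 calls were lost (adjusted p = 0.925 with an estimated correlation, for each). With slide as a block, which here equals the comparison within slide 1, the medians were -0.51 for histones, -0.38 for ribosomal proteins, 0.20 for NB-ARC proteins, -0.14 for the proteasome and -0.21 for lipid transfer proteins. There 35 histone and 156 ribosomal protein genes passed as lower. Quantile normalization gave smaller medians, -0.34 for histones (36 genes lower, 1 higher), -0.21 for ribosomal proteins (159 lower, 38 higher) and 0.13 for NB-ARC proteins (46 higher, 17 lower). It ended the calls of the proteasome (median -0.05, adjusted p = 0.765) and lipid transfer lists (median -0.03, adjusted p = 0.486). Dim genes rose and bright genes fell in general in this contrast (median 0.159 in the dimmest 2406 genes, -0.215 in the brightest). The NB-ARC, proteasome and lipid transfer lists were not compared with lists matched on signal, so signal bias was not tested for them.

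The single genes that moved most were lower after implantation. Os07g0674800 on chromosome 7, annotated as the AP2 domain transcription factor RAP2.2, stood at a log2 signal of 0.60 ± 0.03 (SD, n = 3) relative to the array's 75th percentile in controls and at -4.22 ± 0.20 in ion beam seedlings. This was a difference of 28.3-fold (log2 fold change -4.82 ± 0.12, SE; limma adjusted p = 5.65e-07). A pair of calcium-binding EF-hand protein genes on chromosome 9 fell together. Os09g0483500 fell 45.4-fold (-5.50 ± 0.32, adjusted p = 4.01e-05), and Os09g0483100 was at least 24.8-fold lower (adjusted p = 9.32e-05), since none of the ion beam arrays measured it well above background. In the same way an early nodulin gene (Os06g0141600) was at least 18.9-fold lower, a 2OG-Fe(II) oxygenase gene (Os07g0194500) at least 9.9-fold lower and a protein kinase gene (Os03g0269300) at least 8.78-fold lower. A plant-specific FAD-dependent oxidoreductase gene (Os08g0519100) fell 16.7-fold (-4.06 ± 0.41, adjusted p = 0.000216). Non-symbiotic hemoglobin 2 (Os03g0226200), an oxygen-binding protein, fell 7.31-fold (-2.87 ± 0.30, adjusted p = 0.000237).

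The largest increases were seen in genes that were dim in controls. An aspartic peptidase gene (Os03g0439900), measured on all arrays, rose from -6.21 ± 0.13 to -2.97 ± 0.27 (SD, n = 3), or 9.41-fold (log2 fold change 3.23 ± 0.13, SE; limma adjusted p = 9.6e-06). Genes not well above background on any control array included an eggshell protein family gene (Os10g0455100, at least 15.5-fold higher, adjusted p = 0.000869), a ubiquitin domain gene (Os09g0483200, at least 6.0-fold higher), a cellulase gene (Os08g0387400, at least 5.2-fold higher) and an elongation factor 2 gene (Os01g0723000, at least 2.51-fold higher). A haem peroxidase gene, Os05g0134800, was above background on 1 of 3 control arrays and rose by a log2 fold change of 4.30 ± 1.11 (adjusted p = 0.0115), but did not pass with slide as a block (3.75 ± 1.58, adjusted p = 0.119). The same held for 3 peroxidase genes below background in all controls: Os03g0368300, at least 5.55-fold higher (adjusted p = 0.0905 with the block), Os03g0368000, at least 5.29-fold (0.127), and Os05g0135000, at least 4.0-fold (0.0822).

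**Figure D1:**
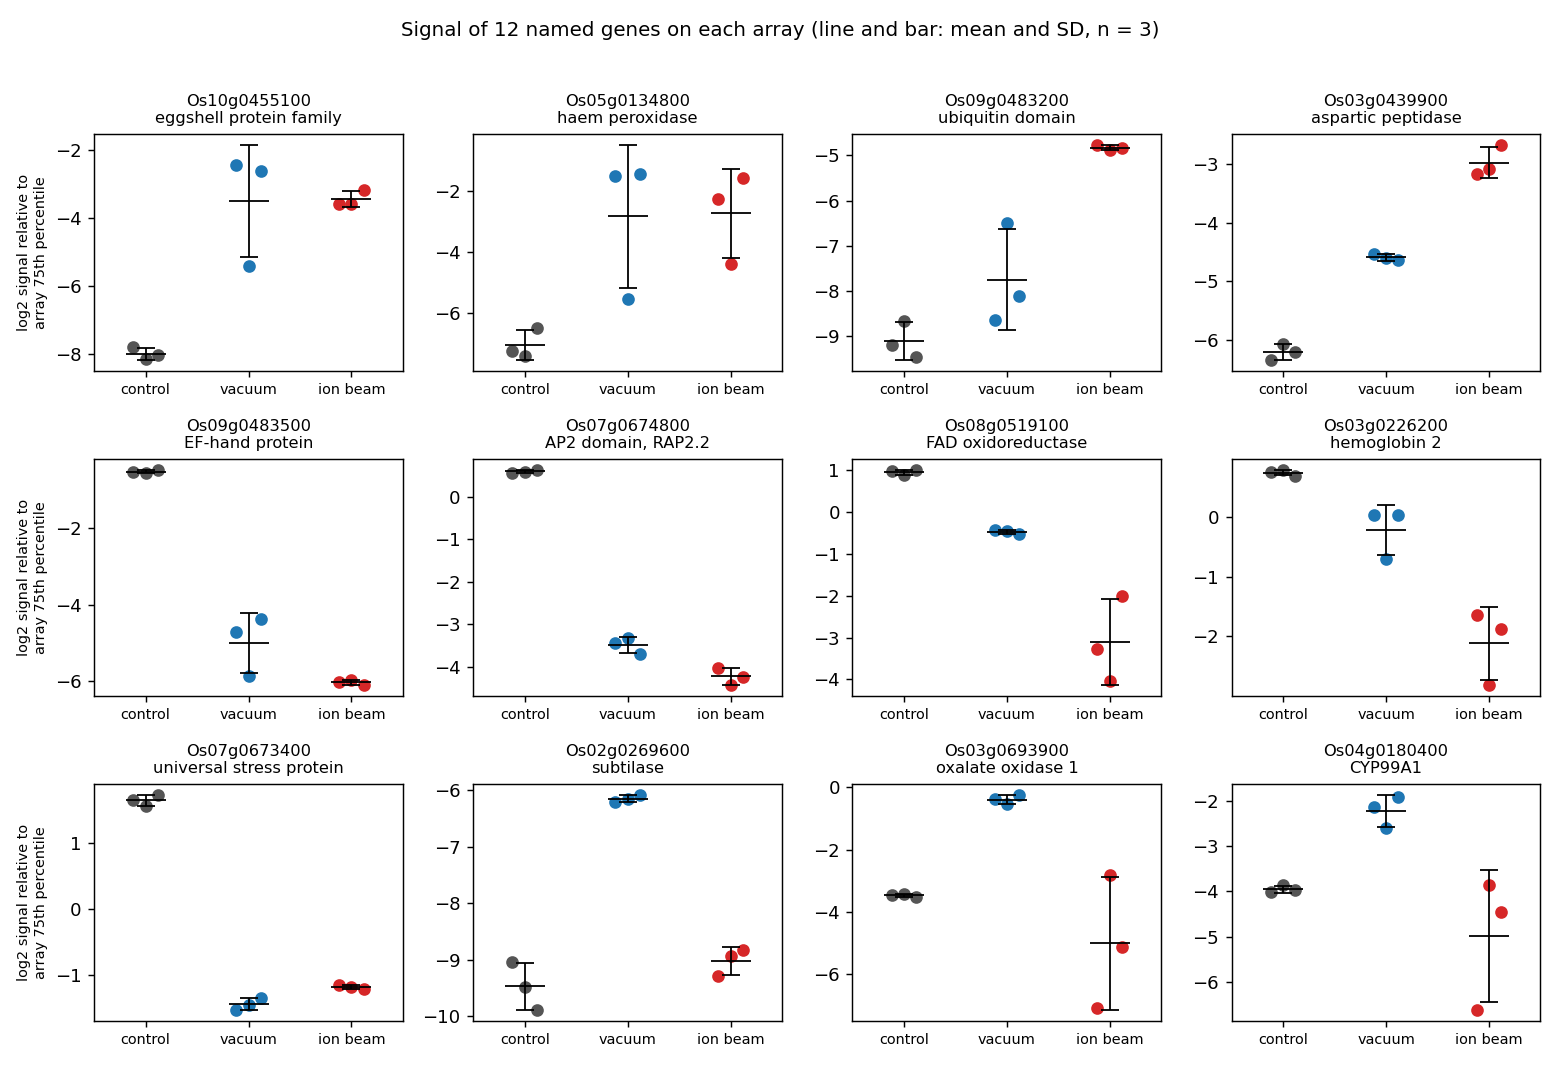
Log2 signal relative to the array's 75th percentile (vertical axes) of 12 genes in control, vacuum and ion beam seedlings, one point per array, with the mean as a long line and the SD (n = 3) as a bar. Os07g0674800 lay near 0.60 in controls and at -4.22 in ion beam seedlings, while the subtilase gene Os02g0269600 stood apart only in vacuum seedlings among these 3 groups.

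Stress and damage lists moved in both directions after implantation, as did genes in general (6428 higher and 5794 lower of 24052, one probe a gene). None of these lists passed the camera test. The fry test, which does not set a list against other genes, called DNA repair (fry adjusted p = 0.00977), antioxidant enzymes (0.00422) and heat shock proteins (0.00538) as higher. It did not call low-oxygen genes (0.937), defence genes (0.774) or late embryogenesis abundant proteins (0.19). Fry was run with the main scaling only. With arrays centred on their medians the list medians fell from 0.12 to 0.0436 (DNA repair), 0.106 to 0.0295 (antioxidant enzymes) and 0.0768 to 7.27e-06 (heat shock proteins). Among 70 DNA repair genes 26 rose, 10 fell and 34 did not pass (also 26 and 10 when adjusted over the list alone; camera adjusted p = 0.385). With quantile normalization 15 rose and 13 fell. A mismatch repair MutS gene (Os10g0509000) rose (log2 fold change 0.87 ± 0.07, SE, n = 3 and 3; limma adjusted p = 0.000112). A RecA family gene (Os05g0121700), of a family that acts in homologous recombination, fell (-0.89 ± 0.06, adjusted p = 7.87e-05). Of 45 antioxidant enzyme genes 16 rose and 11 fell (16 and 12 when adjusted over the list alone; camera adjusted p = 0.634). The risers included thylakoid ascorbate peroxidase (Os02g0553200, 1.02 ± 0.09) and chloroplast 2-Cys peroxiredoxin (Os04g0416400, 0.84 ± 0.07), which remove peroxides, and glutathione reductase (Os03g0163300, 0.69 ± 0.06). Of 141 heat shock protein genes 45 rose and 20 fell (44 and 19 adjusted over the list alone; camera adjusted p = 0.244), among them a DnaJ gene (Os06g0716100, 1.06 ± 0.09) and an Hsp70 gene (Os06g0212900, -0.73 ± 0.06). Fermentation and low-oxygen genes split evenly, with 21 of 65 higher and 21 lower (21 and 22 adjusted over the list alone; camera adjusted p = 0.885). Pathogenesis-related and defence genes numbered 29 higher and 40 lower among 131 (29 and 40 adjusted over the list alone; camera adjusted p = 0.634). Late embryogenesis abundant proteins, which protect drying seeds, numbered 6 lower and 1 higher among 25 (4 and 1 adjusted over the list alone; camera adjusted p = 0.102).

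Markers of the tissues that a whole seedling can hold in different shares also moved both ways, as genes did in general. Over all 24052 genes, one probe a gene, 6428 were higher and 5794 lower. Seed storage and oil body genes numbered 6 higher and 8 lower among 32 (5 and 8 adjusted over the list alone; camera adjusted p = 0.665). A glutelin gene (Os08g0482300) fell by 0.55 ± 0.05 on the log2 scale (SE; limma adjusted p = 0.000151). Reserve mobilisation genes of scutellum and aleurone numbered 20 higher and 15 lower among 67 (20 and 15 adjusted over the list alone; camera adjusted p = 0.944). Root-enriched genes numbered 7 higher and 15 lower among 39 (7 and 16 adjusted over the list alone; camera adjusted p = 0.451), with the root-specific RCc2 gene (Os10g0551800) lower (-0.77 ± 0.06) and a root-specific metal transporter gene (Os01g0503400) higher (0.73 ± 0.07).

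In all, 17991 of the 34904 probes (51.5%, from 13040 genes) differed between ion beam and control seedlings by limma with Benjamini-Hochberg adjustment. Of these, 9898 were higher and 8093 lower, so that 55.0% were higher, against 42.5% when each array was centred on its median. Most changes were small, with a median of 1.34-fold, and 1010 probes (564 higher, 446 lower) of 836 genes changed at least 2-fold. The slide block left 9288 probes, and within slide 1, where 3 ion beam arrays met 1 control, 1196 passed. Of the 1010 probes changed at least 2-fold, 798 passed with the block, and 850 kept their direction at 2-fold or more. The mean of the controls as 1 sample, a setting chosen after the data were seen, left 6188 probes, with 32 histone and 106 ribosomal protein genes lower.

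**Figure D2:**
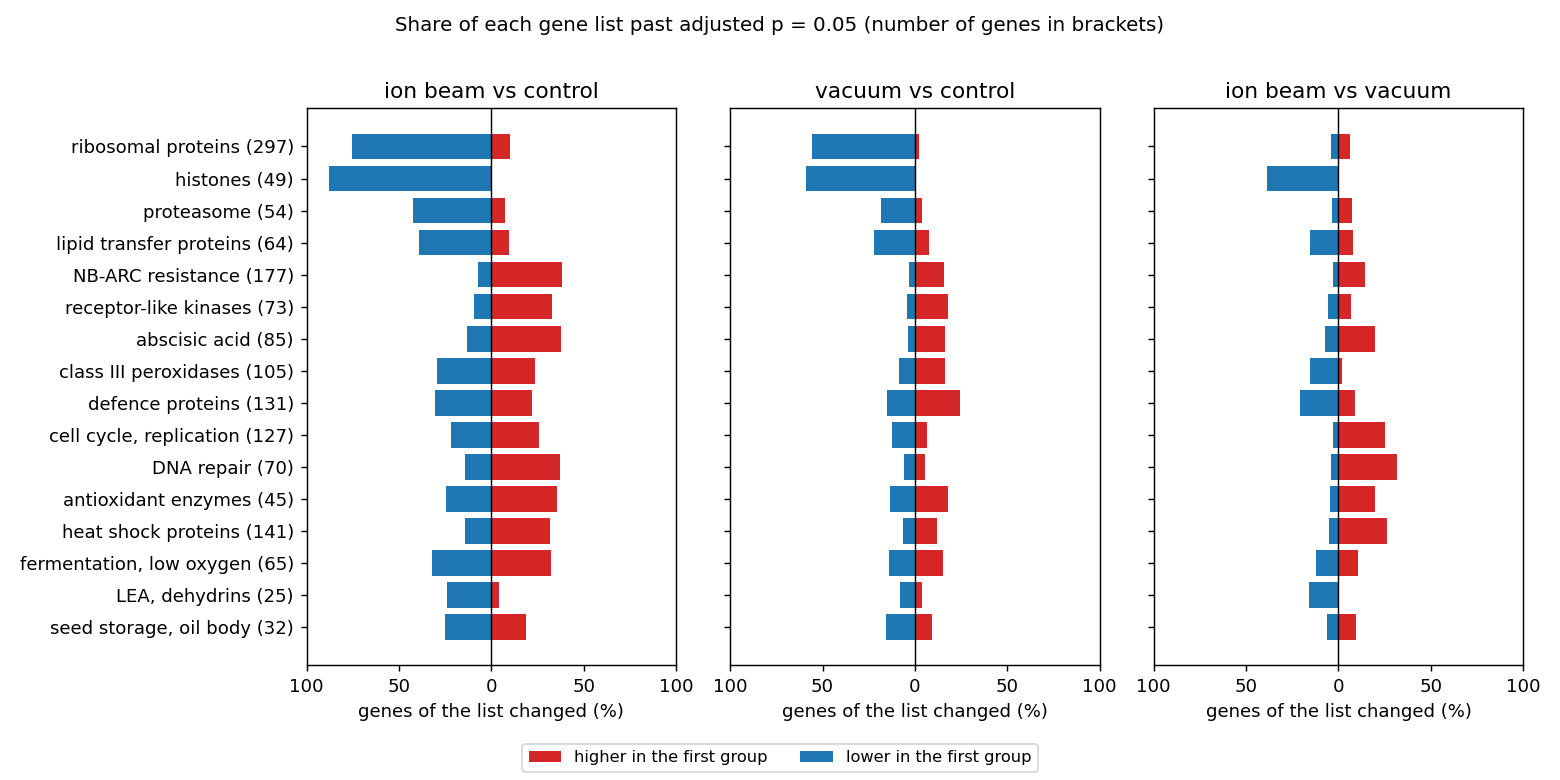
Percentage of the genes in each of 16 lists that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in the 3 contrasts, with the number of genes in brackets. Of 49 histone genes, 43 were lower in ion beam than in control seedlings, 29 were lower in vacuum than in control seedlings and 19 were lower in ion beam than in vacuum seedlings.

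Vacuum seedlings were compared with untreated controls to ask what the vacuum treatment changed on its own. Os07g0674800, the AP2 gene above, fell 17.0-fold (log2 fold change -4.09 ± 0.12, SE, n = 3 and 3; limma adjusted p = 1.38e-06). Among genes annotated as universal stress proteins, Os07g0673400 and Os03g0305400 fell, the first by 8.61-fold (-3.11 ± 0.07, adjusted p = 3.53e-07) and the second by 8.77-fold (-3.13 ± 0.17). The early nodulin 93 gene Os06g0142300 fell 5.74-fold (-2.52 ± 0.07, adjusted p = 9.83e-07). The EF-hand gene Os09g0483500 fell 22.1-fold (-4.47 ± 0.32, adjusted p = 0.000239), and the oxygenase gene Os07g0194500 was at least 9.05-fold lower. A subtilase gene (Os02g0269600), of a family of secreted proteases, was not well above background in controls and was at least 2.39-fold higher in vacuum seedlings (adjusted p = 7.91e-05). The eggshell protein family gene Os10g0454700, measured on 1 of 3 control arrays, rose by 3.51 ± 0.40 (adjusted p = 0.00197). By group means over all arrays, the highest log2 fold change among described genes belonged to an FKBP-type peptidylprolyl isomerase gene (Os01g0564300, 4.57 ± 0.68, adjusted p = 0.00451), which did not pass with slide as a block (adjusted p = 0.0568). Nor did the eggshell gene Os10g0455100, at least 15.0-fold higher (adjusted p = 0.0503 with the block). Both genes stood lower on vacuum 2 than on vacuum 1 and 3 (-3.73 against -1.50 and -1.31 for Os01g0564300, -5.41 against -2.46 and -2.64 for Os10g0455100), and without vacuum 2 their log2 fold changes were 5.35 and 5.46. No control array measured Os10g0455100 well above background, so 5.46 is not a measured fold and the gene's rank is not known. Without vacuum 2 the haem peroxidase gene Os05g0134800 stood at 5.56 (4.21 with it), above Os01g0564300. Over all probes vacuum 2 correlated with vacuum 1 at 0.992, with vacuum 3 at 0.994 and with ion beam 3 at 0.994.

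Histones and ribosomal proteins were lower after vacuum too. Of 49 histone genes 29 fell and 20 did not pass (38 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.29 (SD between genes 0.20). Of 297 ribosomal protein genes 166 fell, 6 rose and 125 did not pass (202 and 15 adjusted over the list alone), with a median of -0.26 (SD 0.19). Examples were the histone H2A gene Os12g0438000 (-0.42 ± 0.05, SE; limma adjusted p = 0.00273) and the L37 gene Os02g0815000 (-0.47 ± 0.05, adjusted p = 0.00209). NB-ARC genes numbered 28 higher and 6 lower among 177 (28 and 6 adjusted over the list alone), and receptor-like kinase genes 13 higher and 3 lower among 73 (16 and 3 adjusted over the list alone). Proteasome genes numbered 2 higher and 10 lower among 54 (2 and 10 adjusted over the list alone), and abscisic acid genes 14 higher and 3 lower among 85 (14 and 3 adjusted over the list alone). Receptor-like kinases that rose included Os06g0288100 (0.46 ± 0.06) and Os12g0632900 (0.49 ± 0.08). In the abscisic acid list, named for the hormone of seed dormancy and water stress, abscisic stress ripening protein 1 (Os02g0543000) rose by 0.89 ± 0.07 (adjusted p = 0.000367) and the EF-hand gene EFA27 (Os04g0511200) fell (-1.31 ± 0.18). The camera test gave adjusted p = 1.81e-17 for ribosomal proteins, 2.86e-10 for histones, 0.00366 for NB-ARC proteins, 0.00428 for receptor-like kinases, 0.00761 for the proteasome and 0.0348 for abscisic acid. All 6 calls were lost with a correlation estimated within each list (adjusted p = 0.925 with an estimated correlation, for each). With slide as a block, equal here to the comparison within slide 2, the medians were -0.25 for ribosomal proteins, -0.31 for histones, 0.16 for NB-ARC proteins, 0.14 for receptor-like kinases, -0.09 for the proteasome and 0.07 for abscisic acid. Under that block 13 ribosomal protein and 2 histone genes passed as lower. The abscisic acid call ended with the block (adjusted p = 0.0908), with quantile normalization (0.0708) and without control 1 (0.0537), vacuum 1 (0.101) or vacuum 3 (0.0635). Quantile normalization also ended the proteasome call (0.381) and gave medians of -0.15 for ribosomal proteins (64 genes lower, 13 higher), -0.19 for histones (14 lower, 1 higher) and -0.04 for the proteasome. The block brought transposable element proteins past the threshold (adjusted p = 0.0401; 0.274 without it, and adjusted p = 0.925 with an estimated correlation), of which 13 of 91 genes were higher and 5 lower (12 and 4 adjusted over the list alone). With the mean of the controls as 1 sample 0 histone and 0 ribosomal protein genes passed as lower by limma (22 and 116 at an unadjusted p under 0.05).

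Defence genes split after vacuum, with 32 of 131 higher, 20 lower and 79 not passing (35 and 22 adjusted over the list alone; camera adjusted p = 0.613; the median was -0.04 and the mean 0.14). Enzymes that break down fungal cell walls were among the risers. The chitinase genes Os04g0493400 and Os04g0494100 rose 3.1-fold and 2.93-fold (log2 fold changes 1.63 ± 0.10 and 1.55 ± 0.08, SE; limma adjusted p = 7.68e-05 and 5.08e-05). The beta-1,3-glucanase gene Os01g0940700 rose 2.7-fold (1.43 ± 0.08, adjusted p = 7.61e-05). DNA repair genes numbered 4 higher and 4 lower among 70 (4 and 4 adjusted over the list alone; camera adjusted p = 0.843), and antioxidant genes 8 higher and 6 lower among 45 (10 and 10 adjusted over the list alone; camera adjusted p = 0.535). Low-oxygen genes numbered 10 higher and 9 lower among 65 (10 and 10 adjusted over the list alone; camera adjusted p = 0.982). Of the tissue markers, seed storage genes numbered 3 higher and 5 lower, reserve mobilisation genes 7 higher and 5 lower, and root-enriched genes 6 higher and 4 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.211, 0.908 and 0.932).

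Vacuum and control seedlings differed at 7855 probes (22.5%, from 6132 genes), 4088 higher and 3767 lower, by limma with Benjamini-Hochberg adjustment. The share that was higher was 52.0%, against 38.2% with arrays centred on their medians. The median change was 1.28-fold, and 374 probes (237 higher, 137 lower) changed at least 2-fold. The slide block left 1071 probes, and within slide 2, with 2 vacuum arrays and 2 controls, 196 passed. Of the 374 probes, 169 passed with the block, while all 374 kept their direction and 319 were still at least 2-fold. The mean of the controls as 1 sample left 58 probes. The count was 2793, 3710 and 3538 without controls 1, 2 and 3, and 4802 and 4833 without vacuum 1 and 3.

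**Figure D3:**
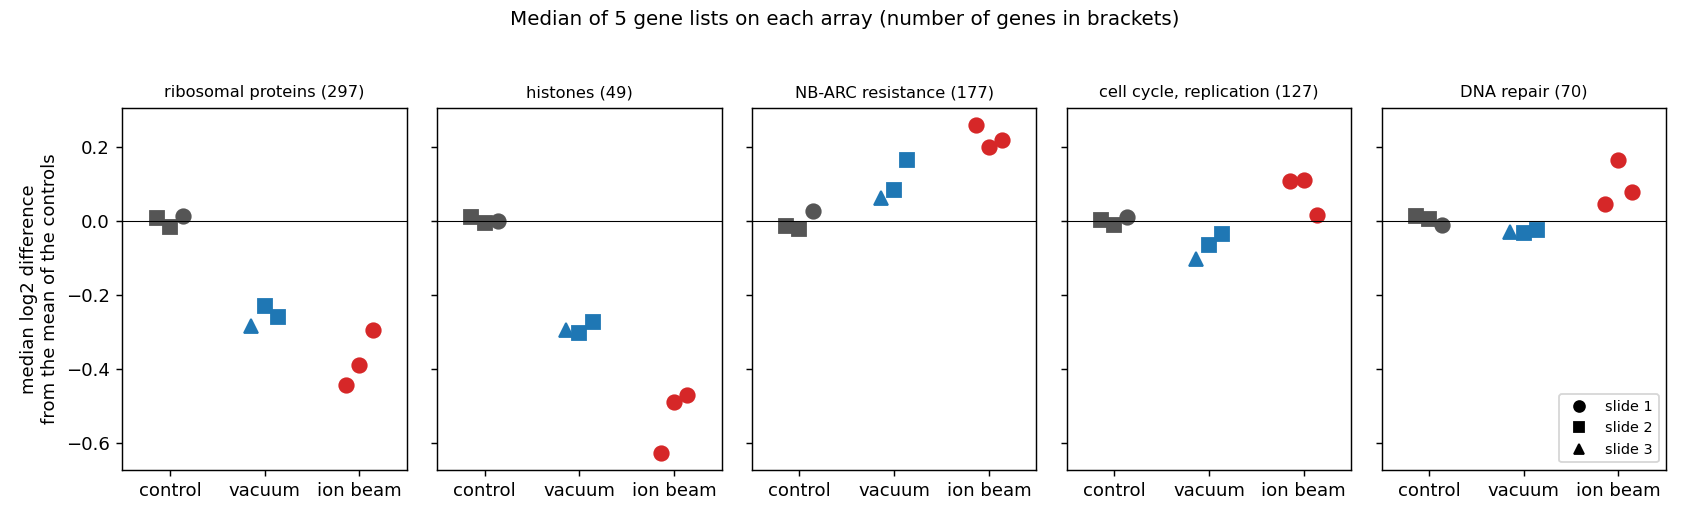
Median log2 difference from the mean of the 3 controls (vertical axis) of 5 gene lists on each of the 9 arrays, grouped by treatment, with the marker shape giving the slide. For ribosomal proteins and histones every vacuum array lay below every control array, and the ion beam arrays lay lowest.

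Ion beam and vacuum seedlings were compared to ask what the ions added to the vacuum. Before slide was taken into account, histones were again lower, with 19 of 49 genes lower and 30 not passing (30 lower when adjusted over the list alone; median log2 fold change -0.24). They included an H4 gene (Os05g0466600, -0.54 ± 0.10, SE, n = 3 and 3; limma adjusted p = 0.0109) and an H1 gene (Os04g0253000, -0.35 ± 0.07). Cell cycle and DNA replication genes moved the other way, with 32 of 127 higher and 4 lower (35 and 5 adjusted over the list alone; median 0.10). Examples were DNA polymerase alpha (Os01g0868300, 0.50 ± 0.08, adjusted p = 0.00737) and a type A cyclin gene (Os05g0237100, 0.41 ± 0.06). Defence genes numbered 27 lower and 12 higher among 131 (32 and 13 adjusted over the list alone; median -0.13), and class III peroxidases 16 lower, 2 higher and 87 not passing (16 and 1 adjusted over the list alone; median -0.08). Lipid transfer proteins numbered 10 lower and 5 higher among 64 (10 and 5 adjusted over the list alone; median -0.11). The chitinase gene Os04g0494100 was lower than in vacuum seedlings (-0.61 ± 0.08), and a thaumatin-like gene (Os03g0663400) was higher (0.76 ± 0.09). The peroxidase genes Os01g0963000 and Os07g0677200 were lower (-1.34 ± 0.16 and -0.88 ± 0.11). Ribosomal proteins had 18 genes higher and 12 lower among 297 (3 and 1 adjusted over the list alone) and a median of -0.11. That median is close to the -0.10 of the brightest 2406 genes in this contrast, and of 10000 random lists matched on signal 1232 were as low.

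Genes with the largest differences between ion beam and vacuum seedlings included oxalate oxidase 1 (Os03g0693900), a germin that makes hydrogen peroxide from oxalate. It stood at a log2 signal of -0.39 ± 0.15 (SD, n = 3) in vacuum seedlings and -5.01 ± 2.14 in ion beam seedlings, where 2 of 3 arrays measured it well above background (log2 fold change -4.61 ± 0.85, SE; limma adjusted p = 0.0102). The SE rests on a spread pooled over all groups, controls included, and is small beside the SD of 2.14. In vacuum against control seedlings this gene had a log2 fold change of 3.07, so the difference includes a rise after vacuum. A cytochrome P450 gene (Os02g0570700) was at least 2.88-fold lower (adjusted p = 0.00206) and the subtilase gene Os02g0269600 at least 2.19-fold lower (adjusted p = 0.00178) in ion beam than in vacuum seedlings. A P450 gene annotated as CYP99A1 (Os04g0180400) was lower too (-2.75 ± 0.59, adjusted p = 0.0161), but did not pass without vacuum 3 (adjusted p = 0.0515). Heat shock factor RHSF2 (Os08g0546800) was 4.44-fold higher (2.15 ± 0.33, adjusted p = 0.00662), and the elongation factor 2 gene Os01g0723000 was at least 2.1-fold higher (adjusted p = 0.00395). DNA repair genes numbered 22 higher and 3 lower among 70 (24 and 5 adjusted over the list alone; camera adjusted p = 0.111), including the MutS gene Os10g0509000 (0.51 ± 0.07). Heat shock genes numbered 37 higher and 7 lower among 141 (40 and 14 adjusted over the list alone; camera adjusted p = 0.234). Seed storage genes numbered 3 higher and 2 lower, reserve mobilisation genes 9 higher and 6 lower, and root-enriched genes 2 higher and 5 lower (3 and 2, 9 and 6, and 2 and 3 adjusted over the list alone; camera adjusted p = 0.7, 0.938 and 0.116).

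The camera test gave adjusted p = 5.41e-10 for histones, 4.22e-05 for ribosomal proteins, 0.00761 for lipid transfer proteins, 0.0142 for class III peroxidases, 0.0168 for defence and 0.0435 for the cell cycle. Each of the 6 calls was lost with a correlation estimated within each list (adjusted p = 0.925 with an estimated correlation, for each). With slide as a block the medians were -0.21 for histones, -0.13 for ribosomal proteins, -0.17 for lipid transfer proteins, -0.10 for class III peroxidases, -0.20 for defence and 0.11 for the cell cycle. No slide held both groups, so no value within a slide could be had. The peroxidase call ended with the block (adjusted p = 0.0908) and without vacuum 1 (0.0586) or ion beam 2 (0.273). The cell cycle call ended without control 1, 2 or 3 (0.0532, 0.0544 and 0.0569), vacuum 1 or 2 (0.0602 and 0.0755) or ion beam 2 (0.205). Quantile normalization ended the calls of ribosomal proteins (0.305; median -0.06, 29 genes higher and 3 lower) and lipid transfer proteins (0.145), and left 11 histone genes lower (median -0.18). The block brought the DNA repair list past the threshold (camera adjusted p = 0.0156, against 0.111 without it, both at the preset correlation). The unblocked fit gave adjusted p = 0.925 with an estimated correlation.

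In total 8126 probes (23.3%, from 6290 genes) differed between ion beam and vacuum seedlings by limma with Benjamini-Hochberg adjustment, 5124 higher and 3002 lower, and 367 of them (183 higher, 184 lower) by at least 2-fold. The share that was higher was 63.1%, against 47.7% with arrays centred on their medians, and the median change was 1.3-fold. The SEs and p-values of this contrast use a spread pooled over all groups, and the controls, which are not part of it, varied least. Their median SD was 0.06, against 0.10 in vacuum and 0.11 in ion beam seedlings. A fit of these 2 groups alone left 2814 probes. The slide block left 2 probes by limma, and 3797 had an unadjusted p under 0.05. None of the genes chosen by the naming rule for this contrast passed with the block, the lowest adjusted p being 0.391. The folds moved less than the calls: of the 367 probes that differed at least 2-fold, 351 kept their direction with the block and 237 kept at least 2-fold. The 2 probes, named here after their values were seen, were a nuclear transport factor 2 domain gene (Os09g0266000, 3.21 ± 0.18 with the block and -0.15 ± 0.76 without) and a curculin-like lectin gene (Os01g0958200, 4.54 ± 0.20 with the block and 0.36 ± 0.94 without). Without the block, the count was 5158 without control 1, 3687 and 4068 without vacuum 1 and 3, and 4292 and 2967 without ion beam 1 and 2.

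Probes called against the controls after both treatments moved mostly the same way. Of the probes called in both contrasts, 6604 moved the same way (3510 higher, 3094 lower) and 46 moved in opposite ways. The 6604 made up 84.1% of the probes called after vacuum and 36.7% of those called after ion beam. Independent lists of these sizes would share 1159 higher and 873 lower probes, with 2016 opposite. Both contrasts used the same 3 controls. The covariance of the log2 fold changes across probes was 0.11, against 0.01 in 100 simulations of unchanged groups, a difference of 0.10. In the simulations all groups, controls included, were drawn around the control means with each probe's pooled spread, and both contrasts shared the drawn controls. The correlation was 0.68, against 0.50. The simulations cover the spread between arrays, but not a deviation common to all 3 controls. A set of 3 controls cannot be split into 2 sets of at least 2, so such a deviation may make part of the excess. The overlap was 883 probes with slide as a block, and 2427, 3237 and 3113 probes without controls 1, 2 and 3. Among probes called after vacuum, 1743 moved farther in the same direction in ion beam than in vacuum seedlings and 629 moved back, by the direct test of ion beam against vacuum. The vacuum arrays enter both tests with opposite sign. Their spread by itself would thus favour moving back, and the counts cannot be compared as they stand. Both counts rest on a contrast that shared no slide, and with slide as a block they fell to 0 and 0 by limma, where that contrast kept 2 probes (3797 at an unadjusted p under 0.05).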

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

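Counting the controls as 1 sample, adding the last slide position and blocking on the scanner files' numbers were chosen after the results were seen; the other settings were set beforehand. The cause of the differences below was not tested.

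With slide as a block the counts of changed probes were 9288 (ion beam against control), 1071 (vacuum against control) and 2 (ion beam against vacuum, with 3797 at an unadjusted p under 0.05), and the overlap was 883. List calls numbered 17, of which 15 were among those without the block. Within 1 slide they were 1196 and 196 for the first 2 contrasts. Slide as a random block gave 12416 for ion beam against vacuum (consensus correlation -0.12). The replicate number of the sample titles as a block gave 16649, 5464 and 5503 and 16 list calls, ending the cell cycle call (adjusted p = 0.0584), and samples of the same number did not pair. The scanner files number the controls and vacuum samples otherwise, and a block on those numbers gave 17908, 7087 and 7923.

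Array weights gave 27661, 15539 and 16629 probes. A 2-fold limit left 1010, 374 and 367. For ion beam against vacuum, the 2 groups alone gave 2814 and a plain t-test 0 (9708 at an unadjusted p under 0.05). The mean of the controls as 1 sample left 6188 probes in ion beam and 58 in vacuum seedlings, where 749 of 1010 and 52 of 374 probes changed at least 2-fold still passed. Then 32 histone and 106 ribosomal protein genes were lower in ion beam seedlings, and 0 and 0 by limma in vacuum seedlings (22 and 116 at an unadjusted p under 0.05). Last slide position as a covariate gave 16766, 6898 and 6175.

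Of 111 list tests (37 lists in 3 contrasts), 17 passed. An estimated correlation left 0 by camera (1 at an unadjusted p under 0.05) and the fry test called 31. Quantile normalization called 13, of which 11 were among the 17, and added the photosynthesis list in ion beam against control (adjusted p = 0.00125) and against vacuum (0.0352). The fry test did not call abscisic acid after vacuum (0.0509), nor class III peroxidases (0.19), defence (0.0509) or ribosomal proteins (0.19) in ion beam against vacuum. Among the lists that fry, which does not set a list against other genes, called as higher and camera did not were DNA repair, antioxidant enzymes and heat shock proteins. Their fry adjusted p was 0.00977, 0.00422 and 0.00538 in ion beam against control, and 0.00513, 0.0153 and 0.0068 in ion beam against vacuum.

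Leaving out 1 array at a time gave 14058 to 18671 (ion beam against control), 2793 to 9235 (vacuum against control) and 2967 to 11487 probes (ion beam against vacuum), and 14 to 22 list calls. The overlap, for which only the controls were left out in turn, was 2427 to 3237. By array, vacuum against control gave 2793, 3710 and 3538 without controls 1, 2 and 3, and 4802 and 4833 without vacuum 1 and 3; ion beam against vacuum gave 5158 without control 1, 3687 and 4068 without vacuum 1 and 3, and 4292 and 2967 without ion beam 1 and 2.

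Of genes in the text's lists, 73 of 82 (ion beam against control) and 50 of 79 (vacuum against control) passed in the same direction under each of the settings set beforehand that were run on single genes. With the mean of the controls as 1 sample 71 of 82 and 11 of 79 passed. In ion beam against vacuum 77 of 78 lost their call with slide as a block, and 1, the laccase gene Os12g0257800, reversed (log2 fold change 2.23, adjusted p = 0.04; -0.58 with the block).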

Other observations

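The tests of slide, of fewer dividing cells, of signal bias as the whole shift, of matched lists in the contrasts with vacuum and of neighbours by probe distance alone were chosen after the results were seen; those of lists matched on signal in ion beam against control, of similar neighbouring copies and of other splits were set beforehand.

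Further gene groups in ion beam against control seedlings did not pass the camera test, and most held both higher and lower genes. Cell wall growth genes numbered 28 higher and 41 lower among 140 (28 and 41 adjusted over the list alone; camera adjusted p = 0.323). Expansins, which loosen the wall during growth, were among those that fell: OsEXPA5 (Os02g0744200) with a log2 fold change of -1.23 ± 0.08 (SE, n = 3 and 3; limma adjusted p = 6.94e-05) and OsEXPA4 (Os05g0477600) with -0.84 ± 0.07. A cellulose synthase gene (Os07g0551500) fell as well (-1.46 ± 0.10). Auxin response genes numbered 19 higher and 28 lower among 88 (21 and 28 adjusted over the list alone; camera adjusted p = 0.312). They included a GH3 homologue (Os05g0500900, -1.32 ± 0.08), of a family that conjugates auxin to amino acids, and a SAUR gene (Os08g0452500, -0.83 ± 0.05). The AP2/ERF list, picked by description words, numbered 15 higher and 24 lower among 77 (15 and 24 adjusted over the list alone; camera adjusted p = 0.299). In it a gene annotated as an ethylene-responsive coactivator (Os06g0592500) was higher (1.76 ± 0.12) and a binding factor (Os01g0224100) lower (-1.27 ± 0.11). The annotation alone does not show that the coactivator is an AP2/ERF factor. Cell cycle and DNA replication genes numbered 33 higher and 28 lower among 127 (31 and 28 adjusted over the list alone; camera adjusted p = 0.656), among them a kinesin gene (Os03g0773600, 0.66 ± 0.06) and a cyclin gene (Os04g0552300, -0.88 ± 0.08). Class III peroxidases numbered 25 higher and 31 lower with 49 not passing (25 and 32 adjusted over the list alone; camera adjusted p = 0.634), such as Os04g0602100 (0.93 ± 0.08) and Os06g0546500 (-1.30 ± 0.07). Abscisic acid genes numbered 32 higher and 11 lower among 85 (30 and 11 adjusted over the list alone; camera adjusted p = 0.0898), with abscisic stress ripening protein 1 (Os02g0543000, 0.83 ± 0.07) and zeaxanthin epoxidase (Os04g0448900, 0.72 ± 0.09) among the risers.

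Photosynthesis genes, in seedlings grown in the dark, numbered 34 higher and 14 lower among 95 (33 and 14 adjusted over the list alone; camera adjusted p = 0.329). Quantile normalization gave 48 higher and 13 lower and passed the test (adjusted p = 0.00125; without it, adjusted p = 0.925 with an estimated correlation), while median centring turned the list's median from 0.07 to -0.01. An oxygen-evolving complex gene of photosystem II (Os08g0347500) rose (0.72 ± 0.06, SE; limma adjusted p = 0.000112), and the gene of its 22 kDa protein (Os04g0690800), which helps dissipate excess light, fell (-1.14 ± 0.12). Reference genes (actins, tubulins, elongation factors) numbered 5 higher and 12 lower among 47 (4 and 9 adjusted over the list alone; camera adjusted p = 0.469), but 9 higher and 2 lower with quantile normalization. Alternative respiration genes numbered 4 higher and 11 lower among 23 (5 and 11 adjusted over the list alone; camera adjusted p = 0.463), and 7 and 6 with quantile normalization. WRKY factors numbered 15 higher and 10 lower among 59 (12 and 9 adjusted over the list alone; camera adjusted p = 0.885), and 9 and 15 with quantile normalization. P450 enzymes numbered 56 higher and 43 lower among 205 (55 and 43 adjusted over the list alone; camera adjusted p = 0.843), and 45 and 50 with quantile normalization.

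Receptor-like kinases numbered 24 higher and 7 lower among 73 (23 and 7 adjusted over the list alone; camera adjusted p = 0.0786), and transposable element proteins 34 higher and 13 lower among 91 (34 and 13 adjusted over the list alone; camera adjusted p = 0.0693). Phenylpropanoid genes numbered 32 higher and 16 lower among 93 (32 and 16 adjusted over the list alone; camera adjusted p = 0.469), and nitrogen uptake and assimilation genes 17 higher and 10 lower among 43 (18 and 10 adjusted over the list alone; camera adjusted p = 0.386). MYB factors numbered 48 higher and 30 lower among 143 (48 and 30 adjusted over the list alone; camera adjusted p = 0.665) and NAC factors 19 higher and 10 lower among 60 (19 and 10 adjusted over the list alone; camera adjusted p = 0.634). Glutathione S-transferases numbered 18 higher and 13 lower among 64 (18 and 13 adjusted over the list alone; camera adjusted p = 0.882), and diterpenoid phytoalexin genes 5 higher and 11 not passing among 16 (4 higher adjusted over the list alone; camera adjusted p = 0.599). Gibberellin genes numbered 4 higher and 8 lower among 22 (4 and 8 adjusted over the list alone; camera adjusted p = 0.469), and ethylene synthesis genes 3 and 4 among 13 (3 and 4 adjusted over the list alone; camera adjusted p = 0.938). Aquaporins numbered 3 and 5 among 18 (1 and 5 adjusted over the list alone; camera adjusted p = 0.472) and metallothioneins 3 and 2 among 15 (1 and 2 adjusted over the list alone; camera adjusted p = 0.936). For class III peroxidases, glutathione S-transferases, WRKY factors, ethylene synthesis, diterpenoids, low-oxygen genes and metallothioneins the median, the mean and the camera test did not all point the same way.

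All ion beam arrays shared slide 1, and if slide were the source of the group differences, control 3, on slide 1, would move away from the other controls as the ion beam arrays did. Over 906 probes measured on all arrays and at least 2-fold apart between ion beam and control 2, chosen without controls 1 and 3, the slope of control 3 minus control 1 on ion beam minus control 2 was 0.0464 (0.0112 to 0.14 over the 12 chromosomes), which argues against slide as the main cause of that contrast. For ion beam against vacuum the slope over 221 probes was 0.097 (-0.0448 to 0.436), and with no slide shared by these groups, the ions and the slide cannot be told apart for this contrast. Among the repeat spots (23 probes with 10 spots), the SD between spots of an array was 0.06 in controls. The SD of the spot means between arrays was 0.03 there, against 0.06 in the vacuum and 0.06 in the ion beam group.

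For the lower ribosomal protein and histone genes in ion beam seedlings, signal bias was weighed first, since bright genes were lower in general (median log2 fold change -0.21 among the brightest 2406 genes, 0.16 among the dimmest). With slide as a block these medians were -0.225 and -0.0258, and with quantile normalization -0.0656 and 0.00524. The 10000 random lists matched on signal had a median of -0.194 (-0.236 to -0.151) for ribosomal proteins and -0.219 (-0.326 to -0.106) for histones, so that signal bias may account for part of the shift and stays open for that part. The lowest of those lists reached -0.287 and -0.399, against -0.385 and -0.534 for the genes themselves, which argues against bias as the whole shift. After vacuum matched lists had medians of -0.108 and -0.123 (list medians -0.26 and -0.29, with 0 of 10000 as low), but for ribosomal proteins in ion beam against vacuum (-0.11) 1232 of 10000 were as low, so that signal bias may account for that shift. For histones in that contrast (-0.241) 0 of 10000 were as low, the lowest list reaching -0.179. Lists other than ribosomal proteins and histones were not matched on signal in any contrast. For ion beam against control, the medians within slide 1 were -0.38 (quartiles -0.507 to -0.241) for ribosomal proteins and -0.513 (-0.607 to -0.408) for histones, which argues against slide. The cell cycle list did not fall as a whole, with a median of 0.0557 (quartiles -0.201 to 0.246). Its median was 0.0219 with quantile normalization and -0.0211 with median centring. That list was picked by description words and not matched on signal. It therefore cannot decide whether fewer cells were dividing, the only biological explanation tested.

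Neighbouring genes changed the same way by at least 2-fold more often than shuffled genes, though rarely: 37 of 24040 neighbouring pairs in ion beam against control (median of 10000 shuffles 11, highest 26) and 19 in vacuum against control (median 1, highest 8). In both contrasts 4 eggshell protein family genes on chromosome 10 rose, with log2 fold changes after ion beam and after vacuum of 2.78 and 2.93 (Os10g0453900), 3.18 and 3.21 (Os10g0454500), 3.59 and 3.51 (Os10g0454700) and 4.55 and 4.50 (Os10g0455100). No control array measured Os10g0455100 well above background and not all measured Os10g0454700, so 4.55 and 4.50 are not measured folds. The probes of Os10g0454500 and Os10g0454700 were only 12 edits apart. By probe distance alone the counts stayed above the shuffles, at 36 (highest 26) and 18 (highest 8) pairs with probes at least 20 edits apart, but a probe may bind the transcript of a similar copy outside the region of that copy's own probe. Among the 8969 such pairs whose descriptions were also not word for word the same, the counts were 7 (shuffles: median 4, highest 13) and 5 (median 0, highest 5). These still held neighbours of the same family, such as oxo-phytodienoic acid reductases and peroxidases after ion beam and beta-1,3-glucanases in both contrasts. The count thus does not set similar copies aside, and their cross-hybridisation stays open. Other pairs, chosen like the eggshell genes after their values were seen, included the hemoglobin genes Os03g0233900 and Os03g0234000 (-1.32 and -1.65 after ion beam).

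Other splits of the 6 arrays of a contrast into 3 and 3 number 10 with the real one, too few for a share under 0.05. Each other split mixes the groups on both sides and so adds their difference to the spread. Few calls would then be found whatever made the groups differ, slide included. In each contrast 1 of 10 splits, the real one, gave as many probes by limma: 17991 against a highest other of 0 for ion beam and control (20244 at an unadjusted p under 0.05 in the real split), 7855 against 1 for vacuum and control, and 8126 against 203 for ion beam and vacuum, the last with vacuum 1, vacuum 3 and ion beam 3 on one side.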
